A study of Mus musculus with 2 samples.

How the data were processed

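MicroRNA sequencing libraries from 2 heart samples of female mice (strain label 5xFAD/CAST, 8 to 10 months) were analysed as 1 group of 2 replicates, as the labels number them. The deposited values are raw read counts per microRNA gene, 1 table per library, with columns for reads regardless of strand, reads on the strand of the gene and reads on the opposite strand. Per the labels' protocols the input was total RNA with a labelled size range under 30, whose unit is not stated. The deposited readme names build mm10 and gene annotation release M21. The aligner and its settings are not given in the sources used here. The first 4 rows of each table hold reads that were unmapped, mapped to several loci, outside the genes or ambiguous, per the row names of the deposited tables, and they stayed out of library sizes and tests. They came to 19.0%, 42.4%, 6.94% and 0% of the 13233055 reads of replicate 1, and 17.5%, 43.2%, 7.11% and 0% of the 8930289 reads of replicate 2. Reads at several loci were thus not assigned to genes, so the counts of genes that share sequence with another locus, such as Mir1a-1 and Mir133a-1, hold only their unique reads. Without strand, 9.67% and 6.38% of reads were ambiguous, because 64 genes overlap a microRNA gene of the other strand.

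The column for the strand of the gene was used, since it held nearly all reads of genes that overlap no other microRNA gene. All 2202 gene identifiers matched the annotation of release M21 (build mm10), which gave symbols, coordinates, host genes and precursor sequences. The host was an annotated gene on the same strand that contained the microRNA gene, a protein-coding host first and then the smallest. A microRNA gene was called exonic if any exon of that host overlapped it, otherwise intronic, and intergenic without a host. Counts per 1000000 (CPM) were computed over the assigned counts, 4186560 in replicate 1 and 2877511 in replicate 2. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.717 and 1.04 CPM. Intervals for shares and ratios are exact 95% Clopper-Pearson intervals. They and the floor cover counting error only, since reads without molecular identifiers are not independent molecules. The libraries were not duplicates: the chi-square statistic over genes was 1901 per degree of freedom.

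A gene counted as detected at 1 CPM in both libraries. The common biological coefficient of variation was estimated with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, estimateDisp, intercept-only design) in R 4.3.3. Each gene kept by that filter was tested for a difference between the libraries with an exact binomial test on its counts given the TMM-scaled totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios are TMM-scaled and given as replicate 2 over replicate 1. A list of microRNA genes was described by its share of counts and, with at least 3 tested members, by the percentile of its median log2 ratio among 10000 random lists of the same size, matched in 10 bins of mean level. Clusters joined genes on a strand with gaps up to 10 kb, and levels entered as log2(CPM + 0.5). Permutation tests used 100000 resamples. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, and DESeq2 1.42.0 gave alternative size factors and dispersions.

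The main tests, the 17 lists and the rule for named genes were fixed before the data were examined. The tests of same-family genes, of the Mir302 genes and of clusters without the Mir302 genes were added after the results were seen. The rule for named genes took the 25 genes with the highest mean CPM, the 5 genes up and the 5 down with the largest log2 ratio among those with a mean CPM of 10 or more and an adjusted p under 0.05, and members of the lists by level. Mir24-1, Mir24-2, Mir27a, Mir27b and the members of the mir-15 group outside the lists are named as examples chosen after their values were seen. Of the listed symbols, Mir486b matched no gene and was not analysed here. No group comparison was made, because the design holds 1 group. Alternatives covered the strand column, leaving out each replicate, the detection threshold, TMM against DESeq2 size factors and plain totals, filters on low counts, the definition of copies, the cluster gap, the pseudocount and the denominator of shares. Alternatives added after the data were seen were genes without an overlapping partner for the opposite strand, and for the copies symbols starting with Mir and the shared run among detected genes. For values with no test, a count or the coefficient of variation was taken as moved beyond 1.5-fold, the correlation beyond its resampling interval, and a share beyond 1 SD of the replicates.

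The steps were tested on simulated data. Counts simulated with a coefficient of variation of 0.4 gave an estimate of 0.392 over 322 genes, and Poisson counts gave 0.00988. In the binomial step, run on 309 genes, 75 of 100 genes changed 1.5-fold and 87 of 100 changed 2-fold were called, with 2 of 109 unchanged genes. The intraclass correlation within clusters averaged 0.464 over 50 simulations with a true value of 0.5, on 147 genes, and the permutation test of same-family genes, on 88 genes, passed in 82% of simulations with a shared part and 6% without.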

Results

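Small RNA, with a labelled size range under 30, was sequenced from the heart of adult female mice of the label 5xFAD/CAST, aged 8 to 10 months. 5xFAD is a transgenic line used to model Alzheimer disease, and CAST is an inbred strain derived from a wild mouse subspecies. The design held 1 group of 2 libraries, described as biological replicates 1 and 2, and no control or comparison group. The data therefore describe which microRNA genes heart tissue contained and how far the 2 libraries differed. The labels give both libraries the same donor identifier, so the spread between these samples can be technical. P-values of differences between the libraries measure departure from counting error in these samples only, and permutation p-values are across genes. MicroRNA genes received 4186560 reads in replicate 1, out of 13233055 reads, and 2877511 in replicate 2, out of 8930289. Counts were per gene, so the arms of a precursor were not separated.

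Among reads unique to a locus, Mir378a, Mir126a and genes of the let-7 family led the heart profile. Reads at several loci, 42.4% of all reads in replicate 1 and 43.2% in replicate 2, were assigned to no gene. Levels and ranks, here and below, leave them out, so microRNAs encoded at several loci can be more abundant than listed. Mir378a, which lies in an intron of Ppargc1b, a coactivator of mitochondrial genes, had the highest mean level with 11.6% ± 1.46 of all microRNA gene counts (SD, n = 2). Mir126a, the microRNA of the endothelial gene Egfl7, followed with 11.1% ± 9.02 (SD, n = 2), with 174314 counts per 1000000 (CPM) in replicate 1 and 46780 in replicate 2. The order differed by library: Mir126a led in replicate 1, where Mir378a had 105618 CPM, and Mir378a led in replicate 2 with 126274 CPM. Mirlet7b took 8.24% ± 2.83, Mir23b 7.18% ± 2.98, Mir23a 5.68% ± 1.57 and Mirlet7g 5.68% ± 0.585 (SD, n = 2). The 10 most abundant genes of each library held 65.9% of its counts in replicate 1 (exact Clopper-Pearson 95% interval 65.8 to 65.9) and 68.4% in replicate 2 (68.4 to 68.5), a mean of 67.1% ± 1.82 (SD, n = 2), and 8 genes were among the 10 in both.

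The 25 genes with the highest mean level held 88.0% ± 0.145 of the counts (SD, n = 2). Below the 6 genes above stood Mirlet7i with 45311 ± 7860 CPM, Mir139 with 44631 ± 12698, Mir143 with 40998 ± 13787, Mir99a with 33652 ± 4942, Mir22 with 31817 ± 32150 and Mir26b with 29902 ± 2182 (SD, n = 2). Mir29a, Mirlet7d, Mir149, Mir30d and Mir30a ranged from 27521 down to 12689 CPM. Mir99b, Mir30e, Mir191, Mir125a, Mir151, Mir140, Mirlet7e and Mir652 ranged from 9227 down to 5615 CPM. By the annotation of build mm10, 12 of the 25 lay in introns of a host gene, 9 overlapped exons and 4 were intergenic. Mir126a lay at chromosome 2, 26591357 to 26591429, overlapping an annotated exon of Egfl7. Mirlet7b lay at chromosome 15, 85707319 to 85707403, overlapping an exon of the noncoding gene Lncppara. Mir23a was intergenic at chromosome 8, 84208518 to 84208592, and Mir139 lay in an intron of Pde2a at chromosome 7, 101475376 to 101475443. With counts that ignore strand, Mir126a, Mir378a, Mir191, Mir30e and Mirlet7e left the 25, because each overlaps a microRNA gene of the other strand and its reads were then counted for neither. Without replicate 2, Mir140, Mir151 and Mir652 left the 25, and without replicate 1, Mirlet7e did. Mir140 stood at 1651 CPM in replicate 1 and 10419 in replicate 2.

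Of the 2202 annotated microRNA genes, 380 reached 1 CPM in both libraries and 1493 had no count in either. Among the detected genes, 164 were intronic, 100 overlapped exons and 116 were intergenic. With 1 count in either library as the threshold, 709 genes were detected.

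**Figure D1:**
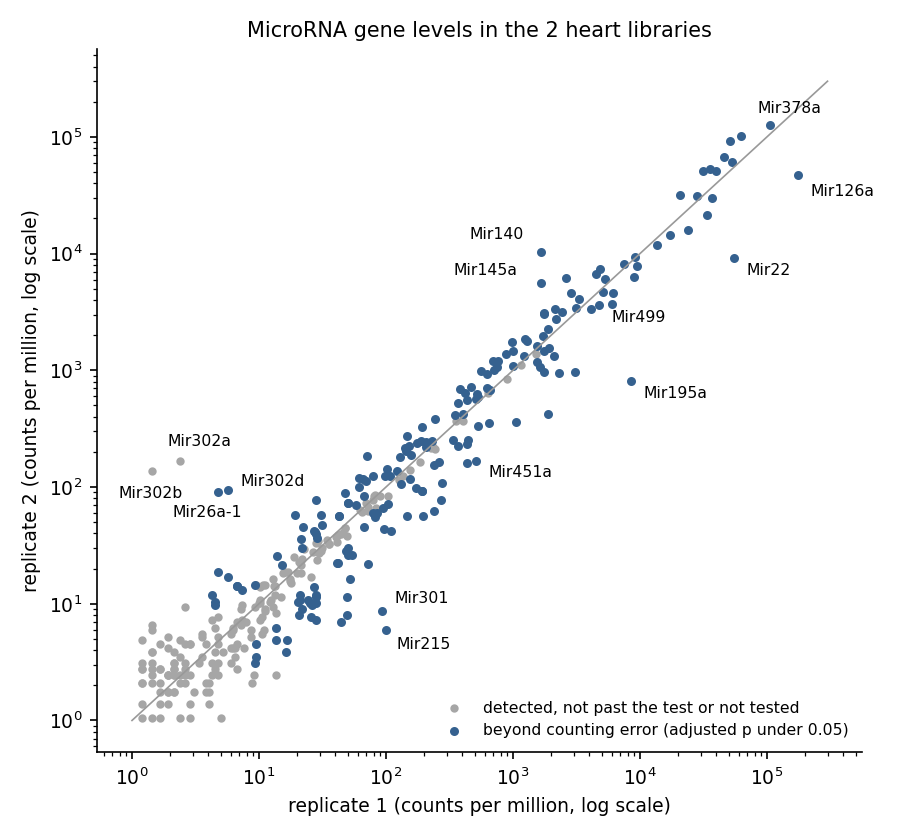
Each point is a detected microRNA gene, with its level in replicate 1 on the x axis and in replicate 2 on the y axis, both in CPM on log scales, and the grey line marks equal levels. Most of the 380 genes lie near the line (Spearman rho 0.942), while Mir126a, Mir22, Mir195a, Mir301 and Mir215 lie below it and Mir140, Mir145a, Mir26a-1 and Mir302a, Mir302b and Mir302d above.

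Heart muscle microRNAs were present, and among reads unique to a locus Mir499 and Mir208a, hosted in myosin heavy chain genes, had the most counts of the list. Mir499, in an intron of Myh7b, stood at 4202 ± 826 CPM (SD, n = 2), and Mir208a, in an intron of Myh6, the main myosin heavy chain gene of the adult mouse ventricle, at 1356 ± 399 CPM. Mir208b, in an intron of Myh7, the myosin heavy chain of the fetal heart, was far lower, at 32.0 ± 13.8 CPM. The 7 genes of the cardiomyocyte list together held 0.567% ± 0.124 of the counts (SD, n = 2), with 0.654% in replicate 1 (exact 95% interval 0.647 to 0.662) and 0.479% in replicate 2 (0.471 to 0.487). Mir499 supplied 74.2% of that share, which came to 0.181% of all reads. Of the 4 members tested, Mir499, Mir208a and Mir208b were lower in replicate 2 beyond counting error and Mir1a-2 did not pass the test. The same 3 passed when adjusted over the list alone.

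Mir1a and Mir133a, the muscle microRNAs that are each encoded by a pair of loci, had very low counts in these tables. Mir1a-1 and Mir1a-2 summed to 72.7 ± 2.98 CPM, and Mir133a-1 and Mir133a-2 to 3.41 ± 0.0928 CPM (SD, n = 2). All 4 genes share a run of 18 bases with another precursor, and reads that fitted several loci were not assigned to genes. The counts of these 4 genes are therefore lower limits. Their CPM values, taken over assigned reads only, set no limit on the microRNAs' levels. The skeletal muscle genes Mir206 and Mir133b stood at 10.0 ± 8.78 and 7.35 ± 0.0754 CPM and together held 0.00174% ± 0.000886 of the counts (SD, n = 2). Mir206 had 68 counts in replicate 1 and was lower in replicate 2, with 11, and Mir133b did not pass the test. Mir133b also shares a run of 18 bases with another precursor, so its count is a lower limit. Its CPM and the list's share, taken over assigned reads only, are not lower limits.

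**Figure D2:**
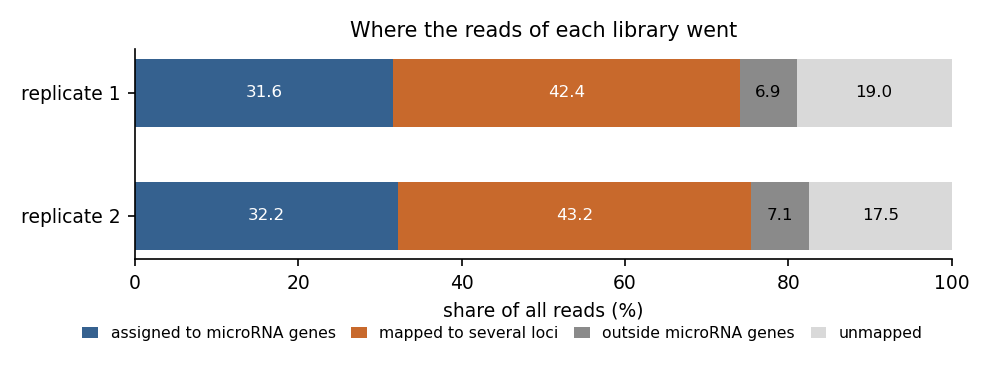
Stacked bars show the share of all reads of each library, in percent, that was assigned to microRNA genes, mapped to several loci, mapped outside microRNA genes or stayed unmapped. Reads at several loci made up 42.4% in replicate 1 and 43.2% in replicate 2, more than the 31.6% and 32.2% assigned to genes.

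Vessel wall microRNAs were abundant, and the most abundant of them, Mir126a, was lower in replicate 2 while the other tested members were higher. The endothelial list (Mir126a, Mir221, Mir222) held 17.6% of the counts in replicate 1 (exact 95% interval 17.6 to 17.7) and 5.00% in replicate 2 (4.97 to 5.02), a mean of 11.3% ± 8.92 (SD, n = 2), of which Mir126a supplied 97.8%. Without regard to strand the list held 0.332%, since Mir126a overlaps a microRNA gene of the other strand. Mir126a was lower in replicate 2 by 1.83 on the log2 scale (log2 ratio -1.83, exact 95% interval -1.83 to -1.82), while Mir221 (log2 ratio 0.89) and Mir222 (0.73) were higher, so the list's summed share and its median ratio of 0.73 differ in sign. The smooth muscle list held 4.46% ± 1.66 (SD, n = 2), nearly all from Mir143, and its tested members Mir143 (log2 ratio 0.77) and Mir145a (1.82) were both higher in replicate 2. Counts adjusted over the list alone were the same for both lists, with 3 of 3 and 2 of 2 members past the test.

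Among reads unique to a locus, fibroblast microRNAs were less abundant, with 0.452% ± 0.111 of the counts (SD, n = 2). Mir21a stood at 2474 ± 389 CPM and was higher in replicate 2 (log2 ratio 0.39). Mir214 stood at 2034 ± 1495 CPM and was lower (log2 ratio -1.59). Mir199b, at 8.04 ± 3.50 CPM, did not pass over all genes tested but passed when adjusted over the list alone, where 3 members passed instead of 2. The Mir199a loci, which share a mature sequence, had 0 and 0 counts at Mir199a-1 and 20 and 2 counts at Mir199a-2. These counts cover only reads unique to a locus and set no upper limit on the level of this microRNA. Mir199b also shares sequence with another precursor, so its count is a lower limit. Its CPM and the list's share, taken over assigned reads only, are not lower limits. Whether fibroblast microRNAs were less abundant than those of the vessel wall once left-out reads are included was not measured.

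Blood microRNAs moved in opposite directions between the libraries. The erythroid genes Mir451a (341 ± 245 CPM) and Mir144 (151 ± 126 CPM; SD, n = 2) were lower in replicate 2, with log2 ratios of -1.54 and -1.88, whereas Mir486, which red cells and muscle both make, was higher (log2 ratio 0.22). All 5 leukocyte genes were higher in replicate 2, led by Mir155 at 3721 ± 566 CPM, a gene of activated lymphocytes and macrophages, and Mir150 at 2394 ± 898 CPM, a gene of mature lymphocytes. Their log2 ratios were 0.38 for Mir155, 0.86 for Mir150, 0.97 for Mir142, 0.68 for Mir223 and 0.24 for Mir342. The erythroid list held 0.154% ± 0.0297 and the leukocyte list 0.717% ± 0.166 of the counts (SD, n = 2). Adjusted over the list alone, 3 of 3 erythroid and 5 of 5 leukocyte genes passed, as over all genes.

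Lists of other organs each held under 0.05% of the counts in either library, although some of their genes were well detected, with Mir128-1 at rank 107, Mir203 at rank 124, Mir137 at rank 150 and Mir122 at rank 183 by mean level. The neuronal list held 0.0305% ± 0.00972 of the counts, mostly Mir128-1, and Mir124a-1, Mir124a-2, Mir124a-3 and Mir9-2 had no count (SD, n = 2). Mir9-3 had 3 counts in replicate 1 and 63 in replicate 2. Except for Mir137, each neuronal gene is a copy that shares sequence with another locus, so these shares and zeros cover only reads unique to a locus and set no upper limit on the microRNAs' levels. Mir137, the single-locus member, held 0.00701% of the counts. The epithelial list held 0.0329% ± 0.00727, led by Mir203 at 127 ± 80.7 CPM. The hepatocyte gene Mir122 held 0.00382% ± 0.00270, with 80 counts in replicate 1 and 165 in replicate 2. The pancreas list held 0.00193% ± 0.000225, almost all from the islet gene Mir375. The pluripotency list differed most, with 0.00112% of the counts in replicate 1 (exact 95% interval 0.000825 to 0.00149) and 0.0425% in replicate 2 (0.0402 to 0.0450), a mean of 0.0218% ± 0.0293 (SD, n = 2). Its counts in replicate 2 came from Mir302a (482 counts), Mir302b (394), Mir302d (270) and Mir302c (77), whereas Mir367, at the end of the same cluster, had 0 in both libraries. Of these genes the test between libraries covered Mir302d alone, because the low counts of the others in replicate 1 kept them below its filter.

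**Figure D3:**
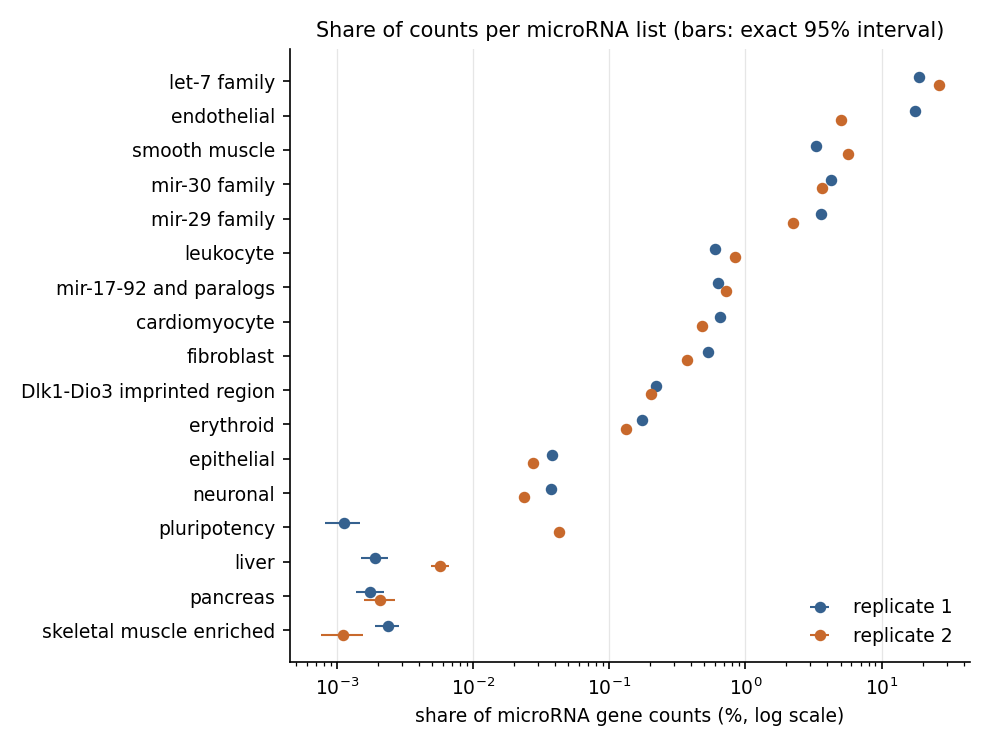
Points give the share of microRNA gene counts, in percent on a log scale, that each of the 17 lists held in replicate 1 (blue) and replicate 2 (orange), with exact 95% intervals that cover counting error only. The let-7 family leads with 18.9% and 26.2%, the endothelial list follows with 17.6% and 5.00%, and the pluripotency list shows the widest gap.

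The let-7 family was the largest family measured, with 22.6% ± 5.14 of the counts (SD, n = 2). Of all reads, unassigned ones included, it held 7.22%. All 12 members were detected, and Mirlet7b, Mirlet7g, Mirlet7i and Mirlet7d supplied most of the share. In replicate 2, 11 of the 12 were higher and Mirlet7f-2 was lower (log2 ratio -0.08), and all 12 also passed when adjusted over the list alone. Values of members with several loci, here and in the families below, cover only reads unique to a locus. The mir-30 family held 3.93% ± 0.412 and split evenly, with 3 members higher (Mir30b, Mir30c-1, Mir30c-2) and 3 lower (Mir30a, Mir30d, Mir30e). The mir-29 family held 2.92% ± 0.973. Mir29a (log2 ratio -0.59), Mir29b-2 (-0.84) and Mir29c (-1.21) were lower in replicate 2, and Mir29b-1 did not pass. The Mir17-92 cluster and its paralogs held 0.678% ± 0.0640, and the imprinted Dlk1-Dio3 region 0.211% ± 0.0113 (SD, n = 2), led by Mir127 at 873 ± 43.6 CPM.

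In the Mir17-92 group, 5 of 10 tested genes were higher in replicate 2, 2 were lower and 3 did not pass. Mir17 (log2 ratio 0.73), Mir18 (0.68), Mir20a (0.63) and Mir93 (0.47) were among the higher genes, and Mir106b (-0.82) and Mir25 (-1.35) were the lower. In the Dlk1-Dio3 region, 16 of 25 tested genes did not pass, 6 were lower and 3 higher, and 8 instead of 9 passed when adjusted over the list alone. Among the tested members, Mir341 had the lowest log2 ratio, -1.64, and Mir541 the highest, 0.51.

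The libraries ranked genes alike but differed in level by more than counting error at most of the genes that passed a filter on low counts. Across the 380 detected genes, Spearman's rho of CPM was 0.942 (95% interval from resampled genes 0.915 to 0.960). This correlation is across genes, which are not independent replicates. The common biological coefficient of variation, the spread between replicates beyond counting error as estimated by edgeR, was 0.414 over 309 genes, and 0.209 with DESeq2's median gene-wise dispersion. The median gene differed 1.42-fold. In exact binomial tests, two-sided with Benjamini-Hochberg adjustment, 196 of 309 genes differed beyond counting error, 109 higher and 87 lower in replicate 2, and 56 differed more than 2-fold. With no filter beyond 1 count, 209 of 709 genes (29.5%) differed beyond counting error, 101 higher and 108 lower. All 25 of the most abundant genes differed beyond counting error, although 13 lay within 1.5-fold. These tests compare the 2 libraries and not conditions.

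Among the genes tested, the 5 lowest in replicate 2 were Mir215, Mir195a, Mir301, Mir192 and Mir200b. Mir215 (log2 ratio -3.98, exact 95% interval -4.81 to -3.32), Mir192 (-2.57, -3.35 to -1.94) and Mir200b (-2.52, -3.24 to -1.93) are genes of epithelium, kidney and gut and had between 186 and 421 counts in replicate 1. Mir195a had 35586 counts in replicate 1 and 2320 in replicate 2 (log2 ratio -3.33, interval -3.39 to -3.27), and Mir301, in an intron of Ska2, had 388 and 25. Among the genes tested, the 5 highest were Mir26a-1, Mir302d, Mir140, Mir669l and Mir145a. Mir302a (log2 ratio 6.13), Mir302b (6.54), Mir302c (5.57) and Mir9-3 (4.79) had larger ratios but were below the filter of the test. Mir140, hosted by Wwp2 and known from cartilage, had 6911 counts in replicate 1 and 29980 in replicate 2 (log2 ratio 2.73, interval 2.69 to 2.77), and Mir302d had 24 and 270 (4.08, 3.50 to 4.77). Mir26a-1, in an intron of Ctdspl, had 20 and 262 counts (4.29, 3.67 to 5.06), and Mir669l, in an intron of Sfmbt2, had 20 and 54 (2.02, 1.28 to 2.86). Among the most abundant genes, Mir22 was 5.71-fold and Mir126a 3.55-fold lower in replicate 2. Mir26a-1 and Mir669l belong to families whose precursors share sequence, so their counts cover only reads that were unique to one locus.

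Of the 12 lists with at least 3 tested members, 3 had a median log2 ratio outside the central 95% of 10000 random lists matched on size and level. The erythroid median was -1.54 (percentile 0.595), the epithelial median -1.13 (percentile 0.40) and the let-7 median 0.63 (percentile 97.9). The leukocyte median of 0.68 lay inside that range, at percentile 96.1. In the epithelial list, 5 of 8 tested genes were lower in replicate 2, Mir203 was higher (log2 ratio 1.46), and Mir200c and Mir429 did not pass. These percentiles describe the 2 libraries and were not corrected for the 12 lists. The random lists were drawn without regard to clusters, whereas list members can share a cluster, as Mir144 and Mir451a do. Log2 ratios of tested genes were correlated within clusters (intraclass correlation 0.462), so the percentiles can be too extreme. The let-7 median was barely past its upper bound of 0.62. The remaining lists lay inside, with cardiomyocyte at -0.43, endothelial at 0.73, fibroblast at -0.82, neuronal at -0.75, mir-30 at 0.01, mir-29 at -0.71, Mir17-92 at 0.23 and Dlk1-Dio3 at -0.13. With no filter beyond 1 count, the fibroblast median was -1.32 and lay outside (percentile 1.07).

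**Figure D4:**
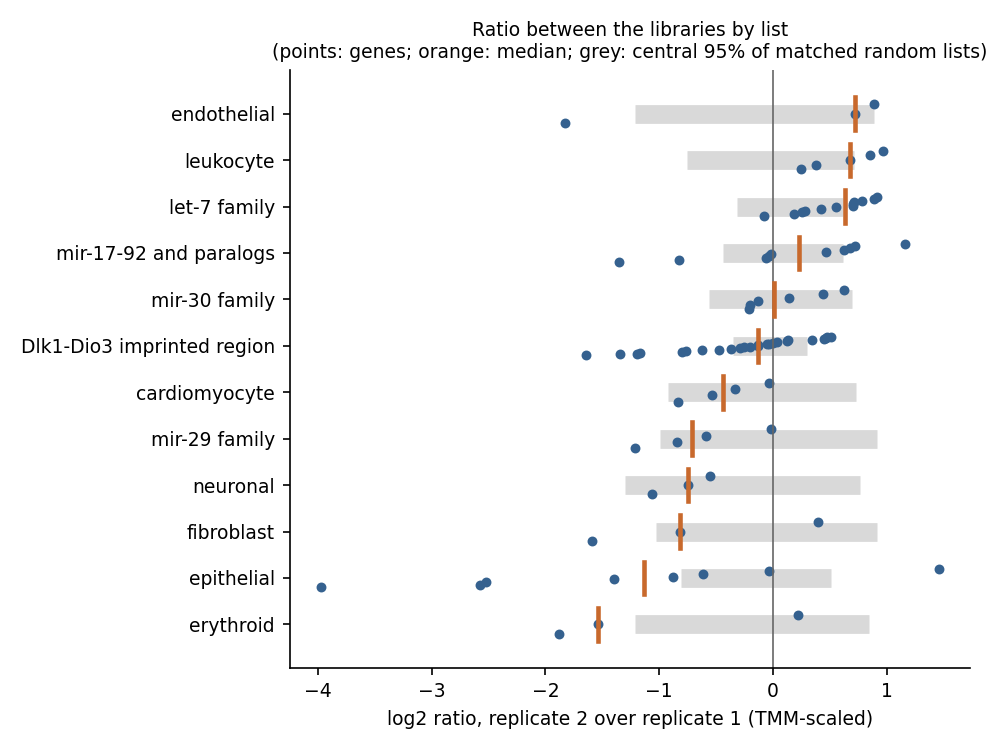
The x axis gives the log2 ratio of replicate 2 over replicate 1 for the tested genes of each list (points), with the list median (orange) and the central 95% of medians of matched random lists (grey). The erythroid and epithelial medians lie below their grey ranges and the let-7 median just above its own.

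Genes of a genomic cluster were closer in level than permuted genes. Detected genes within 10 kb of each other on a strand formed 47 clusters of 147 genes, such as Mir99b, Mirlet7e and Mir125a on chromosome 17, at 9227 ± 230, 5668 ± 523 and 7676 ± 1858 CPM (SD, n = 2). The mean SD of log2 levels within clusters was 2.23, against 3.14 when genes were permuted over the clusters (one-sided permutation p = 0.00012, 100000 resamples). Clusters also held genes of very different level, as with Mir23b at 71849 ± 29846 CPM beside Mir27b at 5376 ± 1098 and Mir24-1 at 122 ± 28.6 CPM. However, Mir24-1 shares its sequence with Mir24-2, so its value covers only reads unique to a locus.

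Whether genes with several identical copies had lower levels was not settled by their median level. By symbol, more genes than not had no count among both the 120 copies and the 2082 others, so both medians were 0 counts and the planned test (difference 0, permutation p = 1) carries no information. Among detected genes, the 45 copies had a median 0.54 higher on the log2 scale than the 335 others (permutation p = 0.442), and among symbols starting with Mir, a set chosen after seeing the data, the difference was -0.43 (permutation p = 0.136); neither passed the test. When copies were defined by a shared run of 18 bases, they were lower over all genes (difference -0.31, permutation p = 1e-05, the smallest that 100000 resamples can give) and, in a comparison chosen after seeing the data, higher among detected genes (1.29, permutation p = 0.0120).

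Reads followed the strand of the genes. At the 2138 genes that overlap no microRNA gene of the other strand, an added restriction chosen after seeing the data, the opposite strand held 129 counts in replicate 1 and 72 in replicate 2, or 0.00444% (exact 95% interval 0.00371 to 0.00527) and 0.00312% (0.00244 to 0.00393) of both strands. Over all 2202 genes the share was 23.4% and 16.5%, a mean of 20.0% ± 4.87 (SD, n = 2), since reads of Mir126a, Mir378a and other abundant genes are counted as opposite for their overlapping partners.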

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

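Of the tests in this part, those of copies over symbols starting with Mir and among detected genes that share 18 bases, of same-family genes at different loci, of the Mir302 genes and of clusters without the Mir302 genes were chosen only after the results were seen. The design holds 1 group, so no explanation that rests on a difference between groups was tested.

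Reads outside the main measurement stood far above the level that a count of 0 allows. Reads that mapped to several loci and were assigned to no gene made up 42.4% of all reads in replicate 1 and 43.2% in replicate 2. Reads mapped once, outside microRNA genes, made up 6.94% and 7.11%. Opposite-strand counts at genes without an overlapping partner came to 129 and 72, with Mir122 in front at 42 and 33 counts against 80 and 165 on its own strand.

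The Mir1a and Mir133a genes, each a pair of loci, had very low counts for heart tissue. Reads at several loci were left out of the gene counts and made up at least 42.4% of each library, but this total does not say which genes they belong to. Genes with copies as a class do not decide it: over symbols starting with Mir, a restriction that avoids the tie at 0 counts, the log2 difference of copies from other genes was -0.43 without passing the test (permutation p = 0.136). By a shared run of 18 bases they were lower over all genes (-0.31) and higher among detected genes (1.29), a set from which copies that lost their reads drop out. These class medians therefore do not decide how many reads Mir1a and Mir133a lost. By the counting itself, reads that match both loci of a pair cannot be counted at either gene. The low counts thus set no upper limit on Mir1a and Mir133a, and how far left-out reads lower them was not measured.

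The 2 libraries differed beyond counting error at 196 of 309 genes. Different amounts of blood were predicted to shift erythroid and leukocyte genes the same way, but the leukocyte median was 0.68 and the erythroid median -1.54 on the log2 scale. The leukocyte median lay inside its random range (percentile 96.1), and the opposite signs argue only against a shared shift of both lists. A difference in red cells alone was not tested. A steady trend with the GC content of the precursors is also argued against, since its Spearman correlation with the log2 ratio over 380 detected genes was 0.0328. The GC content of the sequenced short RNA itself was not measured, so a bias by it was not tested. Genes of a cluster varied together, with an intraclass correlation of 0.672 against a permuted central 95% of -0.203 to 0.213. Without the Mir302 genes it was 0.440, against -0.166 to 0.189. A shared primary transcript may produce this, but clusters can hold genes of the same family, so the correlation does not separate it from shared sequence. Steps that depend on the microRNA's own sequence, such as adapter ligation, also stay open. Same-family genes of different clusters differed by 0.762 on the log2 scale against 0.941 when permuted (one-sided permutation p = 0.0256, 88 genes). That value was close to the edge of the permuted central 95% at 0.761. Different-family genes of a cluster differed by 0.987 against 1.05, which did not pass the test (one-sided permutation p = 0.281). A cluster effect apart from family was therefore not shown.

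Mir302a to Mir302d had 42 counts in replicate 1 and 1223 in replicate 2. Counting error is argued against by the lower 95% bound of the Mir302a log2 ratio, 5.31. Mouse embryonic stem cells that express the Mir290 cluster are argued against too, as Mir290a to Mir295 had 0 counts in replicate 2 (5 in replicate 1), and 3 counts is the limit that 0 allows. Reads from another library handled alongside replicate 2 cannot be told apart from RNA of the sample itself, because the labels name no pool. Beyond the Mir302 genes, 2 further genes with at least 50 counts over both libraries, Mir26a-1 and Mir9-3 (both copies, counted only by reads unique to a locus), were at least 8-fold higher in replicate 2, which may fit such reads or expression in that sample. At the same limits 3 genes, Mir195a, Mir215 and Mir301, were at least 8-fold lower in replicate 2, so genes this far apart were not particular to 1 direction.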

How the results depend on the processing

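Of the alternatives in this part, those restricted to genes without an overlapping partner, to symbols starting with Mir and to detected genes that share 18 bases were chosen after the data were seen. For the results that answer the design, 45 alternative values that keep both replicates stayed on their side, among them values that other scalings or a tie at 0 counts could not move, and 12 did not, and no value called under the main settings turned its direction. For single genes and other lists, 165 stayed, 43 moved and 1 crossed its threshold, the fibroblast median at -1.32 with no filter beyond 1 count. With 2 replicates a value without 1 of them always lies within 1 SD of the mean, so such values say nothing about stability and are given as ranges.

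Counts without regard to strand raised the cardiomyocyte share to 0.760% and the let-7 share to 29.2% and lowered the endothelial share to 0.332%, since Mir126a is then ambiguous with its overlapping partner. As a share of all reads, the cardiomyocyte list held 0.181% and the let-7 family 7.22%, by the larger denominator. Genes detected rose to 709 at 1 count in either library. The coefficient of variation was 0.209 from the median of DESeq2's gene-wise dispersions. This is a different summary from edgeR's common value, so the values are not directly comparable, and how much of the gap it explains was not tested. The correlation was 0.873 over all genes with a count and 0.963 from 10 CPM, by the genes included. Copies that share 18 bases differed by -0.31 over all genes and by 1.29 among detected genes, both past the test in opposite directions, and the cause was not tested. The opposite-strand share was 0.00378% without overlapping genes. With a replicate left out, the endothelial share was 5.00% or 17.6%, the cardiomyocyte share 0.479% or 0.654% and the let-7 share 18.9% or 26.2%.

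The number of genes beyond counting error ranged from 174 of 288 tested, without regard to strand, to 209 of 709, with no filter beyond 1 count. As a share of tested genes it ran from 29.5% with no such filter to 77.0% with at least 100 counts in sum. The balance of direction also moved, from 109 higher and 87 lower in the main setting to 98 and 97 with plain totals. The within-cluster difference ranged from -1.29 to -0.84. The erythroid, epithelial and let-7 medians stayed outside the random range with other filters, and the epithelial and let-7 medians also without strand, where the erythroid list had too few genes. Other scalings shift all genes alike and could not change these calls. Scaling without the low-count filter shifted all log2 ratios by -0.12. No paired analysis was possible because the design holds 1 group. Depth limits genes under 3 counts, 0.717 and 1.04 CPM.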

Other observations

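The mir-15 group and the clusters in this part were chosen after their values were seen, and no further test was run on them.

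In the mir-15 group, whose members share a seed sequence and are known to restrain the cell cycle, 6 of 7 tested genes were lower in replicate 2. The lower genes were Mir15a and Mir16-1 (in Dleu2), Mir15b and Mir16-2 (in Smc4) and Mir195a and Mir497. The exception was Mir322, on chromosome X, which was higher (log2 ratio 0.19). The lower log2 ratios ran from -3.33 for Mir195a to -0.61 for Mir16-2, and all 7 genes passed the exact binomial test. Mir16-1 and Mir16-2 are copies, counted only by reads unique to a locus. Within the cluster of Mir195a and Mir497 the ratios were far apart, -3.33 and -0.78.

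Members of a cluster could also differ in direction. In the cluster of Mir25, Mir93 and Mir106b, Mir93 was higher in replicate 2 (log2 ratio 0.47, exact 95% interval 0.43 to 0.51) while Mir106b (-0.82, -0.95 to -0.70) and Mir25 (-1.35, -1.50 to -1.21) were lower. Mir23a (0.64) and Mir23b (0.94), near-identical microRNAs of different chromosomes, were both higher, and their neighbours Mir27a (-0.22) and Mir27b (-0.35) both lower. The last members of these clusters went apart, with Mir24-2 lower (-1.26) and Mir24-1 higher (0.55), but these are copies of 1 microRNA and the ratios rest only on reads unique to a locus. At the Mir99b cluster, Mir99b (0.12) and Mirlet7e (0.26) were higher and Mir125a (-0.43) lower.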
